A study of Homo sapiens with 15 samples.

How the data were processed

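Neutrophils had been isolated from peripheral blood by density-gradient centrifugation, with lysis of the remaining red cells, and cross-linked with formaldehyde before chromatin immunoprecipitation, per the labels' protocols. Antibodies against acetylated lysine and monomethylated lysine of histone H3 (H3K27ac and H3K4me1) were used. The series held 15 samples: 1 H3K27ac, 1 H3K4me1 and 1 input library from each of 5 patients with active juvenile idiopathic arthritis, 2 of them untreated and 3 treated. Groups were taken from the sample titles. The 5 input libraries had no peak list and were not used here, and the labels of 1 of them contradict each other: the input of untreated patient 2 has an untreated title and a source name that says treated. Title and source name both say untreated for the H3K27ac and H3K4me1 libraries of this patient, who was kept as untreated. The conflict leaves some doubt about this patient's group. Only 1 untreated patient remains without this patient, so sizes are given and no test. Values without the patient are given among the alternatives for peak numbers, covered lengths, region counts, similarities and overlaps of the marks. They are not given for the group comparisons of median peak width, domains of 10 kb or more and chromosome or window shares.

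The deposited files were peak lists, 1 per library, in the broad-peak format. Reads had been aligned with BWA to the hg19 build, per the submitters' processing notes. The peak caller, its thresholds and whether the input served as background are not given in the sources used here. The authors called the peaks separately in each library, since each list carries its library's name, so that patients can be compared as replicates. Each peak in the deposited lists carries several values of its own, which are treated here as a score with no fixed unit: in all 10 lists the last value exceeded the first and the first exceeded the middle one in every peak, an order that fold enrichment, p-value and q-value would not give. The last of these was used as the score. It is the authors' value and served only to rank or filter peaks within a list. The lowest score in any list was 12.2, the narrowest peak was 150 bp wide, and neighbouring peaks lay at least 601 bp apart. The number of reads behind each list is unknown, so no interval for counting error could be given, and a missing peak can mean either little signal or few reads.

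Autosomal peaks were analysed, 543406 of 564318 (96.3%). For each mark the 5 lists were merged into regions wherever peaks overlapped by at least 1 bp, and a region counted as present in a patient whose list had a peak in it. Covered length was also expressed as a share of the autosomes, taken as the span up to the last peak of any list (2880 Mb). Pairs of lists were compared by the Jaccard index, the bases covered in both divided by the bases covered in either. Overlap of the 2 marks within a patient was compared with 20 circular shifts of the peaks along each chromosome. The groups were compared by two-sided exact permutation tests, whose smallest possible p for 2 against 3 patients is 0.2. Counts of regions and similarities were compared over the 10 ways to split the 5 patients, the treatment split included, for which the smallest one-sided exact p is 0.1. The marks were compared within patients by an exact sign-flip test over 32 sign patterns, with a smallest two-sided p of 0.0625. No comparison could therefore pass a threshold of 0.05.

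The tests, the alternatives except those named below as added, and the rule for named regions were fixed before the data were examined. The rule names the 10 widest merged H3K27ac regions with a peak in all 5 patients. It also names, per mark and direction, the 5 regions of a single treatment group with the highest mean within-list percentile of the score, which replaced the fold enrichment planned for this ranking. Gene annotation of the hg19 build was not used here, so regions are given by coordinates (hg19, counted from 1). The 6 planned results that need genes or promoters, among them 25 gene lists, were not run, and the planned share of distal H3K4me1 peaks was computed over all H3K4me1 peaks.

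Alternatives were lists cut to equal length by score (22055 peaks for H3K27ac and 56911 for H3K4me1), autosomes with chromosome X, peaks of at least 500 bp, at least 50% of a region or peak covered, and each patient left out in turn. A score of at least 20 and a common lowest score per mark were added after the data were seen. The counting of regions was tested on simulated data: of 10500 simulated regions, 200 of 200 planted in untreated lists and 300 of 300 planted in treated lists were recovered. The planted regions never touched and had a peak in every list of their group. The test therefore checks the counting and not how many group regions would be found in real lists. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.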

Results

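Active regulatory chromatin was mapped in neutrophils, the most abundant white blood cells of human blood, from 5 patients with juvenile idiopathic arthritis, a chronic inflammation of the joints that begins in childhood. All had active disease; 2 were untreated and 3 were treated, with drugs that are not named in the sources used here. H3K27ac, an acetylation of histone H3 found at active promoters and enhancers, and H3K4me1, a methylation found at enhancers whether active or not, were each measured by chromatin immunoprecipitation and sequencing in every patient. The 10 peak lists held 181946 autosomal H3K27ac peaks and 361460 autosomal H3K4me1 peaks. The read depth of the libraries is unknown, and the label of an input library that was not used casts some doubt on the group of untreated patient 2. The design asks whether the regulatory chromatin of neutrophils differs between untreated and treated active disease.

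H3K27ac peaks covered 2.91% ± 0.977 of the autosomes and H3K4me1 peaks 5.59% ± 1.29 (mean ± SD, n = 5 patients). H3K4me1 had more peaks than H3K27ac in 5 of 5 patients (72292 ± 14233 against 36389 ± 9812), and an exact sign-flip test gave p = 0.0625, the smallest that 5 patients allow. The median H3K27ac peak was 1074 ± 76.8 bp wide and the median H3K4me1 peak 961 ± 30.6 bp, with H3K27ac wider in 4 of 5 patients (difference 113 ± 86.5 bp, exact sign-flip p = 0.125). With only peaks of a score of at least 20 the direction turned, to a difference of -557.8 bp, while equal list lengths raised it to 784.8 bp. Peaks of at least 500 bp raised it to 188.5 bp and a common lowest score lowered it to 70.8 bp. The score of at least 20 and the equal lengths did not cut the marks alike. Median scores were 21.8 ± 2.94 for H3K27ac and 17.6 ± 0.392 for H3K4me1, and lengths were equal only within a mark (22055 and 56911 peaks). These settings therefore cannot decide which mark had the wider peaks. Peaks of 10 kb or more made up 3.26% ± 1.21 of H3K27ac peaks and 3.47% ± 0.370 of H3K4me1 peaks.

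The H3K27ac lists held 38226 ± 3234 peaks in untreated patients (SD, n = 2) and 35165 ± 13480 in treated patients (SD, n = 3). The peaks covered 95.2 ± 20.7 Mb in untreated and 76.4 ± 34.0 Mb in treated patients. Broad acetylated domains of 10 kb or more numbered 1587 ± 633 and 1035 ± 703. None of these differences exceeded the spread between patients, with exact permutation p of 0.8 for peak number, 0.6 for covered length and 0.4 for broad domains. The treated group held both the longest list, 48987 peaks in treated patient 1, and the shortest, 22055 peaks in treated patient 3. Without treated patient 3 the difference, treated minus untreated, went from -3061 to 3493.5 peaks and from -18.8 to -2.17 Mb, and with a score of at least 20 it was -1777 peaks. Leaving out treated patient 1 moved the differences to -9972.5 peaks and -36.2 Mb, untreated patient 1 to -774 peaks and -4.14 Mb, and untreated patient 2 to -5348 peaks and -33.4 Mb.

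H3K4me1 went the other way in its means, with 67137 ± 14462 peaks over 149 ± 43.5 Mb in untreated patients and 75729 ± 16009 peaks over 169 ± 39.7 Mb in treated patients. The differences of 8592 peaks and 19.4 Mb were smaller than the spread between patients (exact permutation p = 0.8 for both). The median H3K4me1 peak was 937 ± 35.4 bp wide in untreated patients (912 and 962 bp) and 977 ± 16.7 bp in treated patients (964 to 996 bp), so that the groups did not overlap (exact permutation p = 0.2, the smallest possible). H3K4me1 domains of 10 kb or more numbered 2429 ± 921 in untreated and 2608 ± 773 in treated patients (exact permutation p = 0.8). The direction rested on single patients: without untreated patient 1 the differences were -1634 peaks and -11.4 Mb, and without treated patient 2 they were -481.5 peaks and -3.36 Mb. They were 18818 peaks and 50.1 Mb without untreated patient 2, and 14653.5 peaks and 33.3 Mb without treated patient 1. With a score of at least 20 they were 1720.5 peaks and 10.3 Mb, and a common lowest score left 5290 peaks.

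**Figure D1:**
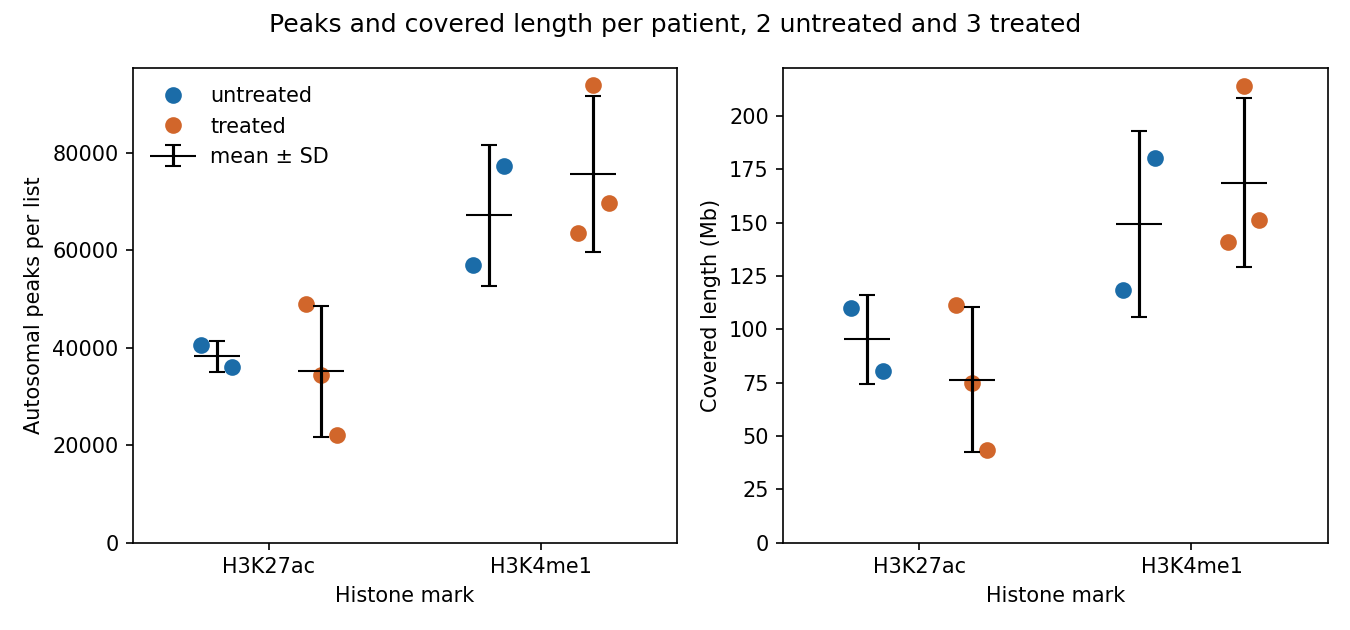
Autosomal peaks per list (left) and the length they cover in Mb (right) for each mark, with 1 point per patient, untreated in blue and treated in orange, and black bars for the group mean ± SD. The treated H3K27ac lists run from 22055 to 48987 peaks and enclose both untreated lists, of 35939 and 40513 peaks.

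A common set of regulatory regions was found in every patient. Merging the H3K27ac lists gave 61358 regions, of which 14121 (23%) had a peak in all 5 patients and 31512 (51.4%) in a single patient. H3K4me1 gave 113730 regions, 26052 (22.9%) of them in all 5 patients and 57352 (50.4%) in a single patient. Regions of a single patient were narrow, with median widths of 426 bp for H3K27ac and 436 bp for H3K4me1. Common regions had median widths of 4938 and 4507 bp, though merging more lists widens a region by construction. Within a list, 60.7% ± 21.4 of H3K27ac peaks and 61.5% ± 15.6 of H3K4me1 peaks lay in common regions (SD, n = 5). Among the 25% of H3K27ac peaks with the highest scores in a list, 97.0% ± 1.46 (SD, n = 5) lay in regions common to all patients, against 35.6% ± 32.1 of the 25% with the lowest scores. The latter mean rested on treated patient 3, whose share was 87.5%, and was 22.6% ± 15.8 over the other 4 lists. For H3K4me1 these shares were 91.2% ± 5.28 and 35.1% ± 19.5.

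Of the 10 widest acetylated regions shared by all 5 patients, 4 lay on chromosome 19, a small chromosome dense in genes. The widest of all spanned 141 kb on chromosome 19, from 41806618 to 41947319, with 68.2 kb covered in every patient. H3K27ac covered 96.0% of this region in untreated patient 1, 75.0% in untreated patient 2, and 91.9%, 70.3% and 51.6% in treated patients 1, 2 and 3. H3K4me1 covered between 94.2% and 99.5% of it in the 5 patients. The next regions lay on chromosome 9 from 137210222 to 137342032 (132 kb), chromosome 20 from 47322224 to 47452526 (130 kb), chromosome 22 from 36744661 to 36872771 (128 kb), chromosome 2 from 70138268 to 70261067 (123 kb) and chromosome 10 from 99070652 to 99192330 (122 kb). The remaining 4 of the 10 were on chromosome 9 from 139412804 to 139525348, and on chromosome 19 from 54656764 to 54762433, from 1034614 to 1137373 and from 47795508 to 47896638. Between 40.8% and 60.5% of each region was acetylated in all 5 patients, and H3K4me1 was present in each region in 5 of 5 patients. Overlaps with the 10 widest H3K4me1 regions were found for 4 of them, on chromosomes 2, 19 (from 1034614 and from 41806618) and 20.

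**Figure D2:**
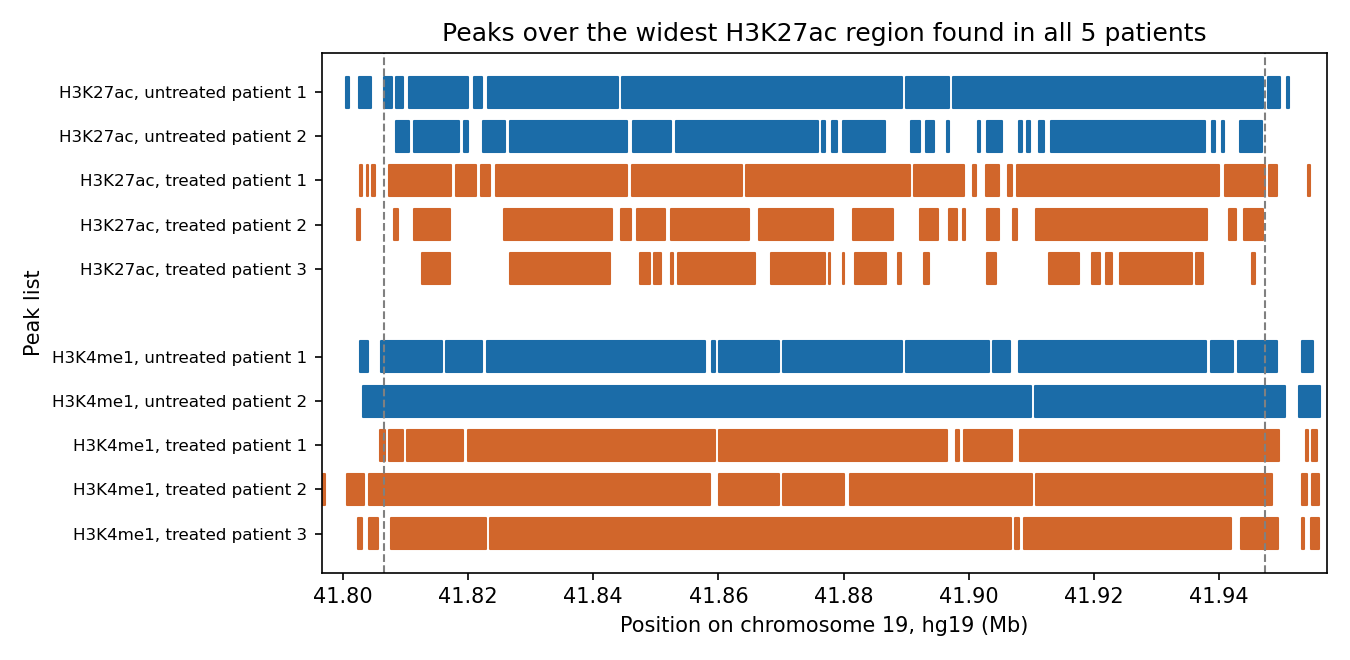
Peaks of the 10 lists over the widest H3K27ac region with a peak in all 5 patients, against the position on chromosome 19 in Mb (hg19); bars are peaks, in blue for untreated and orange for treated patients, and dashed lines mark the ends of the region. H3K4me1 covers at least 94.2% of the region in each patient, and H3K27ac covers from 51.6% in treated patient 3 to 96.0% in untreated patient 1.

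Few regions carried a mark in all patients of a treatment group and in none of the other. For H3K27ac, 712 regions (1.16%) had a peak in both untreated and no treated patients, and 46 (0.0750%) in all treated and no untreated patients. Other ways of dividing the same 5 patients gave as many. With the treatment split itself counted, 4 of the 10 splits reached 712 regions (one-sided exact p = 0.4). The highest other split, 3005, pairs untreated patient 1 with treated patient 1. In the other direction 8 of the 10 splits reached 46 (one-sided exact p = 0.8, highest other split 1357). The median width was 836 bp for the regions of untreated and 1303 bp for those of treated patients. Peaks of these regions ranked low in their lists, at a median score percentile of 25.8 and 31.7. H3K4me1 was nonetheless present in all 5 patients at 304 of the 712 untreated regions (42.7%) and at 15 of the 46 treated regions (32.6%). Without treated patient 3, the shortest list, 939 regions were found in the remaining treated patients only and 737 in the untreated patients only. The untreated and treated counts were 2359 and 94 without treated patient 1, 1112 and 113 without treated patient 2, 5315 and 222 without untreated patient 1, and 10496 and 134 without untreated patient 2. With equal list lengths they were 380 (other splits 83 to 502, exact p = 0.3) and 69 (other splits 80 to 420, exact p = 1), so that the treated count was the lowest of the 10 splits.

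Among the H3K27ac regions of untreated patients, the highest-ranked was on chromosome 2 from 173999219 to 173999834, at the mean percentile 75.4. It was followed by chromosome 3 from 75263617 to 75263816 (74.1), chromosome 11 from 29547957 to 29549224 (64.8), chromosome 3 from 14270540 to 14271181 (63.7) and chromosome 4 from 26360698 to 26361415 (63.1). Among those of treated patients, a region of 3451 bp on chromosome 2 from 72440008 to 72443458 ranked highest, at the percentile 83.9, and H3K4me1 there was likewise found in 3 of 3 treated and 0 of 2 untreated patients. The others were on chromosome 6 from 29893883 to 29894896 (67.5), chromosome 14 from 21358713 to 21360343 (66.8), chromosome 9 from 68454591 to 68455298 (65.0) and chromosome 1 from 92178513 to 92179369 (64.5).

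H3K4me1 showed the opposite balance, with 392 regions (0.345%) in both untreated and no treated patients and 1224 (1.08%) in all treated and no untreated patients. Of the 10 splits, 8 reached 392 regions (one-sided exact p = 0.8, highest other split 5941, which pairs untreated patient 2 with treated patient 2) and 3 reached 1224 (exact p = 0.3, highest other split 2419). Most of these regions lacked H3K27ac in every patient, 276 of 392 (70.4%) and 759 of 1224 (62.0%). The highest-ranked regions of untreated patients were on chromosome 2 from 92281213 to 92281440 (mean percentile 99.6), chromosome 1 from 223351369 to 223351699 (80.1), chromosome 9 from 95911252 to 95911920 (67.8), chromosome 15 from 31731001 to 31731582 (67.4) and chromosome 16 from 89593126 to 89594352 (67.0). Those of treated patients were on chromosome 12 from 133841487 to 133841887 (percentile 99.96), chromosome 21 from 48119437 to 48119945 (84.0), chromosome 17 from 33478078 to 33478327 (81.4), chromosome 10 from 135486263 to 135487710 (81.2) and chromosome 13 from 99701939 to 99704867 (79.9). The regions on chromosomes 12 and 21 had H3K27ac peaks in all 5 patients, whereas the untreated region on chromosome 9 had them in 2 of 2 untreated and 0 of 3 treated patients. The chromosome 12 region lies within a place, from 133841437 to 133841946, where top-scoring peaks of both marks fell together. Whether reads map uniquely at the ranked regions of either mark was not examined, so high percentiles there cannot be read as strong regulatory sites. Without treated patient 2 the counts were 1531 untreated and 2453 treated regions, and a score of at least 20 left 193 and 368. Without untreated patient 1 they were 12877 and 1856, without untreated patient 2 they were 4015 and 6170, without treated patient 1 they were 562 and 3758, and without treated patient 3 they were 644 and 2825.

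**Figure D3:**
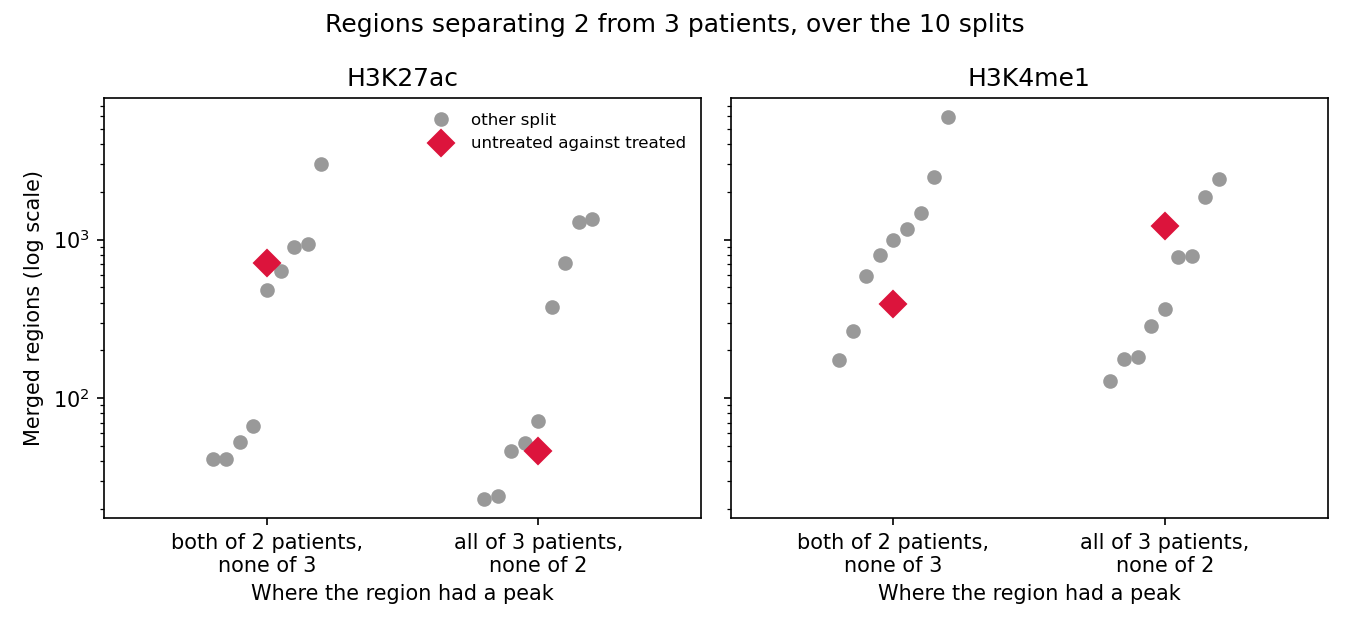
Merged regions with a peak in both of 2 patients and none of the other 3, or in all 3 and neither of the 2, for each of the 10 ways to split the 5 patients (log scale); red diamonds mark untreated against treated patients and grey points the other splits. The 712 H3K27ac regions of untreated patients lie below the highest other split of 3005, and the 1224 H3K4me1 regions of treated patients below the highest other split of 2419.

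Peak lists did not group by treatment. The mean Jaccard index of H3K27ac lists was 0.514 within groups (4 pairs) and 0.546 between groups (6 pairs), a difference of -0.0320 that 6 of the 10 splits reached (one-sided exact p = 0.6). The most similar H3K27ac lists were those of untreated patient 2 and treated patient 2 (0.648) and of untreated patient 1 and treated patient 1 (0.615). The index cannot exceed the shorter covered length divided by the longer, so it also reflects list size. The lowest H3K27ac index, 0.375, joined treated patients 1 and 3, whose lists covered 111 and 43.2 Mb. It lay close to that limit and cannot be read as peaks at different positions. For H3K4me1 the index was 0.55 within and 0.564 between groups, a difference of -0.0134 reached by 7 of the 10 splits (exact p = 0.7), with the highest value between treated patients 1 and 3 (0.627). The H3K27ac difference turned to 0.0374 without treated patient 1, and the H3K4me1 difference to 0.00978 without untreated patient 2 and to 0.00544 without treated patient 2. Without untreated patient 2 the H3K27ac difference was -0.0360.

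**Figure D4:**
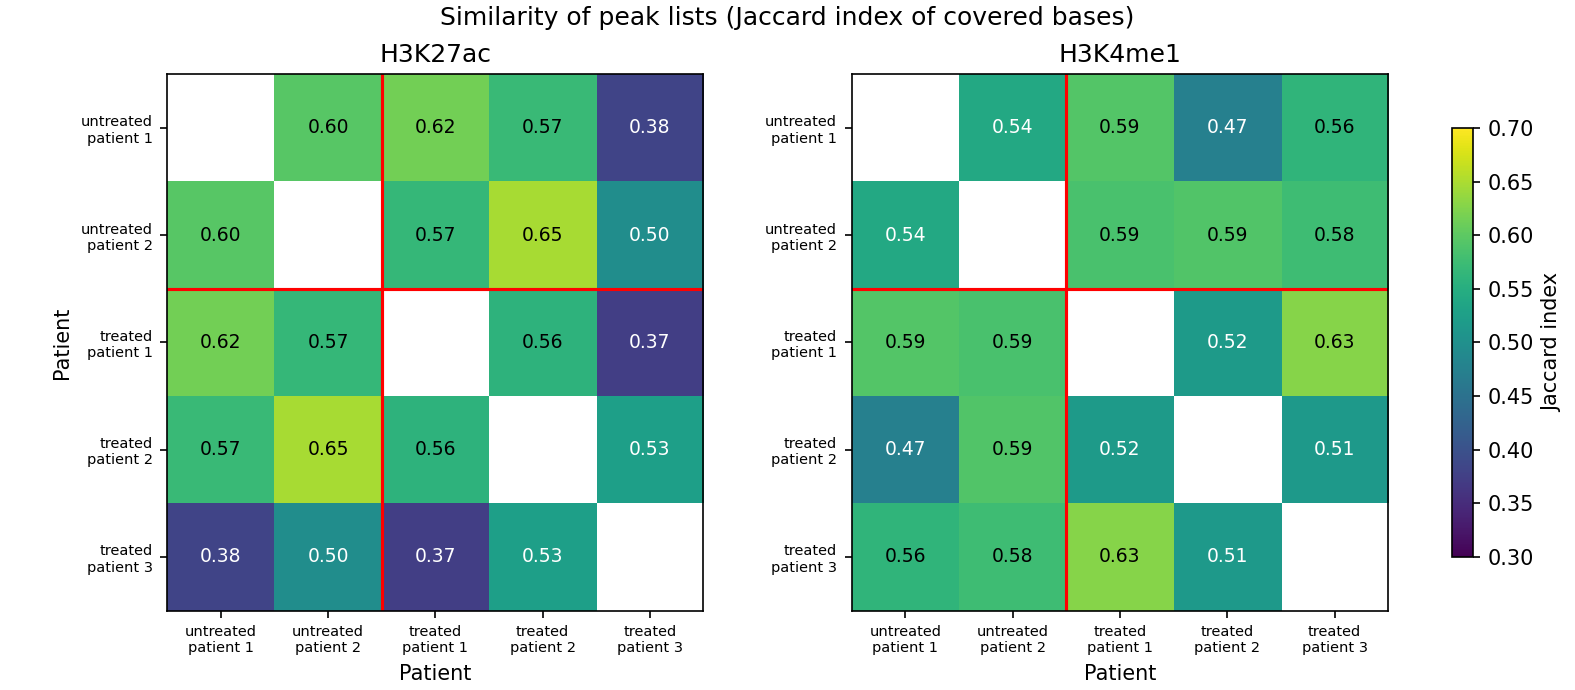
Jaccard index of covered bases for each pair of patients, H3K27ac on the left and H3K4me1 on the right, coloured from 0.3 to 0.7, with red lines between untreated and treated patients. The highest H3K27ac index, 0.648, joins an untreated and a treated patient, and the lowest, 0.375, joins treated patients 1 and 3. The lists of these 2 treated patients covered 111 and 43.2 Mb, and the index cannot exceed the shorter covered length divided by the longer.

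Acetylation sat largely on H3K4me1-marked chromatin. Within a patient, 82.2% ± 12 of H3K27ac peaks overlapped an H3K4me1 peak (SD, n = 5), from 68.8% in untreated patient 1 to 92.4% in treated patient 3, whereas peaks shifted along the chromosomes overlapped in 9.02% to 14.4% on average. Peaks with H3K4me1 were wider than those without, at median widths of 1458 ± 261 bp and 434 ± 46.7 bp. Overlap counted from 1 bp, so wider peaks were more likely to overlap by their width alone, and the shifts were not compared by width. In the reverse direction, 38.5% ± 13.8 of H3K4me1 peaks overlapped H3K27ac, against 3.48% to 7.68% after shifting. Of the 14121 H3K27ac regions common to all patients, 13180 (93.3%) had H3K4me1 in all 5 patients and 46 (0.326%) in none. Of the 26052 common H3K4me1 regions, 13381 (51.4%) had H3K27ac in all 5 patients, 8409 (32.3%) in some and 4262 (16.4%) in none.

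Treatment groups differed in neither overlap beyond the spread between patients. The share of H3K27ac peaks with H3K4me1 was 78.8% ± 14.2 in untreated and 84.4% ± 13 in treated patients (exact permutation p = 0.4). The share of H3K4me1 peaks with H3K27ac was 44.2% ± 14.9 in untreated and 34.8% ± 14.8 in treated patients (exact permutation p = 0.4). The differences of 5.55 and -9.43 percentage points turned to -4.47 and 1.09 without untreated patient 1. They were 15.6 and -19.9 without untreated patient 2, 13.1 and -17.9 without treated patient 1, 2.05 and -5.89 without treated patient 2, and 1.54 and -4.49 without treated patient 3. Equal list lengths left 2.18 and -4.36 points, and a score of at least 20 gave 8.98 and -6.42 points.

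**Figure D5:**
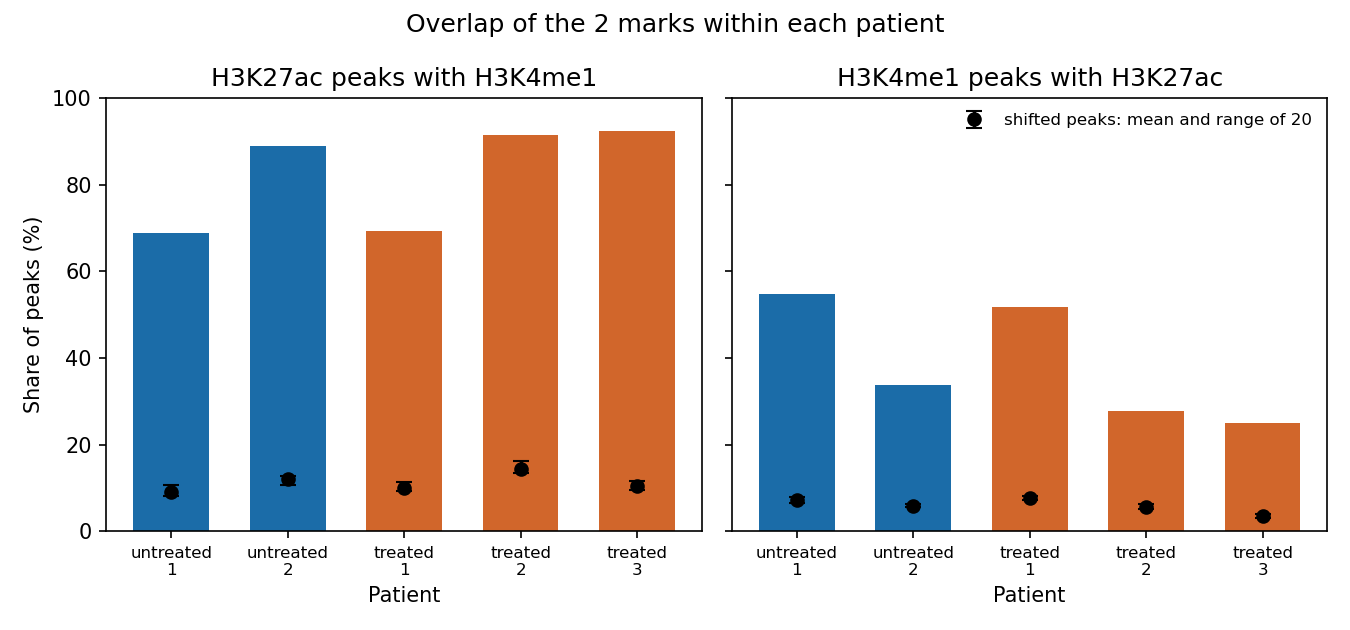
Share of H3K27ac peaks that overlap H3K4me1 (left) and of H3K4me1 peaks that overlap H3K27ac (right) in each patient, in percent, untreated in blue and treated in orange; black points and bars give the mean and range of 20 circular shifts. Each bar, from 24.9% to 92.4%, stands above its shifted peaks, whose means run from 3.48% to 14.4%.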

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

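The values in this part were chosen for reporting only after they were seen, and no explanation was tested. Peaks were also called on sequences outside the chromosomes, which the comparisons left out. The unplaced contig gl000220 held 48 H3K27ac peaks and 82 H3K4me1 peaks over the 5 lists of each mark, the H3K27ac peaks with 1 each in untreated patient 1 and treated patient 1, 12 in untreated patient 2, 18 in treated patient 2 and 16 in treated patient 3. The H3K4me1 peaks there had a median score percentile of 99.98 in their lists (mean of 5 lists), and the H3K27ac peaks one of 92.5. Alternative haplotype contigs held 3158 H3K27ac peaks and 3991 H3K4me1 peaks, at median percentiles of 63.4 and 34.1.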

How the results depend on the processing

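Among the alternatives, a score of at least 20 and a common lowest score were chosen after the data were seen. No setting could bring a test past 0.05 with 2 against 3 patients, so only directions and sizes are compared. Of 134 alternative values, 96 kept their direction or stayed within 1.5 times the count, 27 counts moved further and 11 differences reversed. The planned q-value threshold of 5 was not run, because its column could not be identified and it would remove no peak: the lowest of all values per peak, in any column and list, was 8.15. Equal list lengths fix the peak number and gave no value for it. Alternatives that need genes or promoters were not run.

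H3K27ac regions of untreated patients only numbered 380 with equal list lengths, 474 with peaks of at least 500 bp and 404 with a score of at least 20, against 712. Those of treated patients only numbered 26 with peaks of at least 500 bp, 23 when a peak had to cover at least 50% of the region and 24 with a score of at least 20, against 46. For H3K4me1, regions of untreated patients only numbered 251 with peaks of at least 500 bp and 193 with a score of at least 20, against 392, and those of treated patients only 368 with a score of at least 20, against 1224. Stricter filters leave fewer peaks by construction. The width difference between the marks turned from 113 to -557.8 bp with a score of at least 20, and the cause was not tested. This threshold lay below the mean of the median H3K27ac scores (21.8) and above that for H3K4me1 (17.6), so it cut the marks unequally.

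Leaving out each patient in turn gave H3K27ac differences (treated minus untreated) from -9972.5 to 3493.5 peaks and H3K4me1 differences from -1634 to 18818 peaks and from -11.4 to 50.1 Mb. Region counts, which rise because fewer lists have to agree, ran from 737 to 10496 (untreated) and 94 to 939 (treated) for H3K27ac, and from 562 to 12877 and 1856 to 6170 for H3K4me1. Similarity within minus between groups ran from -0.0832 to 0.0374 for H3K27ac and from -0.0312 to 0.00978 for H3K4me1. Overlap differences ran from -4.47 to 15.6 percentage points for H3K27ac peaks and from -19.9 to 1.09 for H3K4me1 peaks. The cause of these reversals was not tested. The H3K27ac covered length kept its direction in 10 of 10 alternatives. Read depth, which is unknown, limits the meaning of a missing peak.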

Other observations

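The patterns in this part were noticed in the data. Equal list lengths and leaving out a patient were settings fixed before the data were examined, but their use to weigh the similarity between lists was decided after the result was seen, and a common lowest score and a score of at least 20 were added then. Both marks were densest on chromosome 19, the most gene-dense human chromosome, which ranked highest in each of the 10 lists. Between the first and the last peak of a chromosome, H3K27ac covered 108 ± 35.5 kb per Mb there and H3K4me1 189 ± 37.7 kb per Mb (SD, n = 5 patients), followed by chromosome 22 with 78.9 ± 26.4 and 151 ± 35.3 kb per Mb and chromosome 17 with 68.8 ± 23.4 and 139 ± 31.7 kb per Mb. Chromosomes 4 and 13 were the sparsest, with 12.6 ± 4.10 and 12.9 ± 4.16 kb per Mb of H3K27ac and 24.1 ± 6.76 and 25.8 ± 7.39 kb per Mb of H3K4me1. Their order turns when the short arm without peaks on chromosome 13 is counted. Counting the stretch without peaks at the start of chromosome 22 likewise lowers its values to 53.0 and 101 kb per Mb, below those of chromosome 17. Among windows of 1 Mb, the most acetylated was on chromosome 11 from 65000001 to 66000000, with 347 ± 119 kb covered, and the window with most H3K4me1 was on chromosome 19 from 1000001 to 2000000, with 538 ± 103 kb. H3K27ac was in none of the 5 lists in 643 of 2894 windows, and H3K4me1 in none in 448, unsequenced stretches included.

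Some wide H3K4me1 regions were common to all 5 patients and carried no H3K27ac peak in any; the widest 3 are named here after their values were seen. They lay on chromosome 8 from 6822908 to 6885183 (62.3 kb, 40.1 kb of it covered in all 5 patients), chromosome 1 from 161407300 to 161444541 (37.2 kb, 22.5 kb) and chromosome 1 from 837170 to 865237 (28.1 kb, 8.49 kb). Unique mapping of reads in these 3 regions was not examined, so the missing H3K27ac peaks cannot be read as a lack of acetylation. The converse class, H3K27ac in all 5 patients without H3K4me1 in any, was small and narrow, with 46 regions of median width 729 bp. Its widest members were on chromosome 16 from 88142342 to 88145236, chromosome 6 from 28890307 to 28892665 and chromosome 5 from 172570989 to 172572879. Only 162 of 2895 bp, 515 of 2359 bp and 446 of 1891 bp of them were covered in all 5 patients. The top 0.1% of peaks by score in at least 3 lists of both marks fell together at 3 places. They were on chromosome 1 from 121483997 to 121485481, chromosome 5 from 9967 to 11858 and chromosome 12 from 133841437 to 133841946. The place on chromosome 5 began with the first peak of that chromosome in any list. Whether reads map uniquely at the 3 places was not examined, so their scores cannot be read as strong regulatory sites.

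Chromosome 19 held 7.28% ± 0.0322 of the H3K27ac covered length in untreated and 7.94% ± 0.0719 in treated patients (exact permutation p = 0.2, the smallest possible, adjusted over 22 chromosomes 0.4). The groups lay apart on 11 of 22 chromosomes for H3K27ac (highest other split 8) and on 9 for H3K4me1 (highest other split 14), where 20% would lie apart by chance, and 10 splits are too few for a share under 0.05. In windows of 1 Mb the H3K27ac share was higher in all treated patients in 118 windows (other splits 128 to 310) and lower in 263 (138 to 334), so the windows set the treatment groups no further apart than other splits. The lowest treated share stayed above the highest untreated share by 0.246 points with equal list lengths and by 0.226 points with a score of at least 20, in both cases less than the untreated SD (0.264 and 0.240), so list length and weak peaks stay open, while the gap was 0.589 points with peaks of at least 500 bp and 0.569 points with a common lowest score, against 0.574 points with all peaks and group SDs of at most 0.0719. The H3K4me1 share of chromosome 19 was 6.91% ± 0.0568 in untreated and 7.04% ± 0.667 in treated patients, and the groups overlapped. A shift of acetylation under treatment and a sequence bias of the libraries are candidate explanations that were not tested.

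H3K27ac lists were no more similar within than between treatment groups. The difference in Jaccard index stayed below 0 with equal list lengths (-0.0235), with a common lowest score (-0.0314) and without the shortest list (-0.0222), but each value was smaller than the SD over the splits (0.0463, 0.0480 and 0.0455). With all lists the difference of -0.0320 was also smaller in size than its SD over the splits (0.0481), so the criterion was not met even before any change of setting. The comparison with the SD therefore could not decide, and list length, score threshold and the shortest list stay open as reasons why lists may not group by treatment. Equal list lengths fixed the peak number and not the covered length, which enters the index. The covered length, treated minus untreated, still differed by -17.8 Mb there, against -18.8 Mb with all peaks. That setting therefore could not remove an effect of covered length. Without treated patient 1 the difference in Jaccard index was 0.0374. The 3005 H3K27ac regions shared by untreated patient 1 and treated patient 1 alone, against 712 for the untreated patients, came from the 2 longest H3K27ac lists, and with equal list lengths the highest count of any other split was 502, against 380.

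The share of H3K27ac peaks with H3K4me1 ranged over 23.6 percentage points, with 68.8% in untreated patient 1 and 69.4% in treated patient 1 against 88.9% in untreated patient 2 and 91.4% and 92.4% in treated patients 2 and 3; the same 2 patients had the highest shares of H3K4me1 peaks with H3K27ac, 54.7% and 51.7% against 33.7%, 27.7% and 24.9%. The range was 6.43 points with both lists at equal lengths, 8.41 points with only the H3K27ac lists at equal lengths and 10.3 points against the merged H3K4me1 regions of all 5 patients. Each was smaller than the main range but between the bounds set beforehand, under 6 points for a full explanation and 12 points or more for none. With a score of at least 20 the range was 24.7 points. Against the merged regions a share can only rise, and the shares of 91.4% and 92.4% had little room to. The range there would therefore shrink whether or not lists were incomplete. Equal lengths removed the lowest-scoring peaks, so list length and peak strength changed together. The smaller ranges thus do not show that list length or incomplete H3K4me1 lists caused the spread. Both stay open, and no biological explanation was tested.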
